A study of Drosophila melanogaster with 4 samples.

How the data were processed

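Transcript levels were measured in 2 cultured *Drosophila melanogaster* cell lines, Kc and Mbn2, with 2 biological replicates per line according to the series' design text, which does not say whether a replicate was a separate culture or passage. Each of the 4 samples was hybridised to 1 NimbleGen array in a single colour (Cy3), per the labels. Per the series' design text, the array represents 15634 genes in duplicate, with 12 probes of 60 nucleotides per gene. Per the labels' protocols, the cells were untreated, and total RNA was purified on columns with DNase digestion and copied to cDNA. Kc cells were grown in a serum-free medium and Mbn2 cells in a medium with 10% fetal calf serum, so medium and line cannot be told apart in this design.

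The deposited table holds 1 log2 expression value per transcript and sample, which the authors made with RMA (robust multi-array average), per the submitters' processing notes. RMA as usually run subtracts background, gives all arrays the same distribution of probe values and summarises the probes of a transcript on the log2 scale. Its version and settings, the annotation release and the genome build are not given in the sources used here. The values ran from 3.93 to 15.9, and the sample medians lay between 8.53 and 8.62. The quantiles nearly coincided between arrays, which a quantile step produces and which removes any difference in total RNA signal per array. No detection call, control probe or single probe value was used here, so a value near the bottom of the scale shows only that a transcript was dim. Background can compress the differences of dim transcripts, and the number of arrays, 4, limits the precision of every value.

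The rows are named by FlyBase transcript identifiers and carry no gene symbols. Names came from a RefSeq gene table (Release 6 plus ISO1 MT), which holds full transcript identifiers among the synonyms of some genes. It paired 49 identifiers with genes, of which 44 were on the array. Of these, 17 had 1 gene symbol and 27 had several, because the table lists them as transcripts that carry an upstream and a main open reading frame of separately named genes. The other 15590 transcripts are unnamed here. The set of 44 was made by which identifiers the table records, not by expression, and is no random sample of the genome. No coordinates are printed, because the files name no genome build. Table rows could not be collapsed to genes as planned, so every row was tested separately. The design text counts 15634 genes, as many as there are rows, but without names it could not be checked whether several rows belong to 1 gene.

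The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values without further normalization, with all 4 samples and no covariate. Differences are Mbn2 minus Kc. p-values were adjusted by the Benjamini-Hochberg method over all 15634 transcripts, and an adjusted p under 0.05 is called a difference; counts at a difference of at least 2-fold are given as well. Every adjusted p below comes from this limma fit unless another setting is named. The test was checked on simulated data made from the real means and the fitted spread. When 200 changed transcripts were hidden among 15634, it called 98% of those changed 4-fold and 52% of those changed 2-fold, and none of those changed 1.5-fold or 1.25-fold. With so few changed, the adjustment is stricter than in the real data, where 7530 transcripts passed. These shares therefore do not carry over to the real data. In another simulation 6254 of 15634 were changed, by amounts drawn only from the differences called in the real data. Of the changed transcripts 86.5% were called, and 3.13% of the calls were false. Since uncalled differences were left out of the draw, the 86.5% does not tell how many true changes the test finds. The noise was independent with the fitted spread, and unchanged transcripts had no true difference at all. The 3.13% is therefore no estimate of the share of false calls in the real data.

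Before the data were examined, the samples, the test, the alternatives, 47 gene lists and the rule for named genes were fixed. That rule takes up to 12 genes per direction with the largest difference among transcripts with 1 symbol, past the threshold and with both samples of a line above both of the other. From each list it takes up to 2 per direction among members past the threshold. The lists could not be tested, since none had 5 identified members. Only 4 had any, with 1 each (trithorax group, lipid uptake and storage, extracellular matrix, and respiratory chain). The planned comparison of X-linked with autosomal genes was not made for want of names. Transcripts with several symbols and any others outside the rule were chosen after their values were seen. So were the limits of dim (a line's mean under 6) and bright (over 8), which were set from the shape of the distribution.

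The alternatives were a replicate block, an intensity trend with a robust prior, no moderation of the variances, array weights, a second quantile normalization, median centring, leaving out the dimmest 25% of transcripts or those below the median, log2(value + 16), an adjusted p under 0.01, limma's treat against a fold of 1.5, and leaving out each sample in turn. Centring on transcripts over 9 in both lines and limits of 5.5 and 9 for dim and bright were added after seeing the data. Ranges given for single transcripts over the alternatives leave out the adjusted p under 0.01 and treat. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for names, patterns and plots.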

Results

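The series compared steady-state transcript levels in 2 established *Drosophila* cell lines. Kc is a line derived from embryos, and Mbn2 is a line derived from the blood cells of larvae with the tumour mutation l(2)mbn. Each line was represented by 2 arrays, and each array gave a log2 RMA value for 15634 transcripts. Replicates of a line correlated across transcripts at r = 0.996 in Kc and r = 0.997 in Mbn2, whereas arrays of different lines correlated at r = 0.911 to 0.914; transcripts are not independent replicates, so these values only describe the arrays. The median absolute difference between replicates was 0.13 log2 units in Kc and 0.12 in Mbn2. The SD of the replicate difference was 0.26 in Kc and 0.23 in Mbn2, against an SD of 1.26 for the difference between the line means. No value was identical between any 2 samples.

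The 2 lines differed in the level of many transcripts, some of them bright in one line and near the bottom of the scale in the other. Of the 15634 transcripts, 3314 were higher in Mbn2 cells and 4216 were higher in Kc cells (adjusted p under 0.05, limma), 48.2% of those tested. At least 2-fold differences were found for 1634 transcripts higher in Mbn2 and 1591 higher in Kc. RMA values at least 8-fold apart were found for 437 transcripts higher in Mbn2 and 261 higher in Kc, and 61 and 28 were at least 64-fold apart. The files give no background level, so where a line's value was dim the size of the difference is that between RMA values, with no fold given for single transcripts, and the order of such differences is not known. The examples here were chosen after the values were seen, as the 2 transcripts per direction with RMA values farthest apart, and none of them is named. FBtr0071777 was at 14.92 ± 0.07 in Kc and 5.40 ± 0.05 in Mbn2 (log2, SD, n = 2), and FBtr0083508 was likewise higher in Kc, with a difference of -9.43. FBtr0077467 was at 5.78 ± 0.01 in Kc and 14.55 ± 0.02 in Mbn2, and FBtr0076525 was likewise higher in Mbn2, with a difference of 8.30.

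The smallest difference that passed the test was 0.31 log2 units, and 57.2% of the calls were under 2-fold. Both samples of a line lay above both of the other for 72.4% of all transcripts, where chance gives 33.3% for 2 against 2. The same held for every transcript called, but with 2 against 2 samples the threshold itself required it, so it adds no support. The majority of all calls towards Kc depended on the centre chosen. The median difference was -0.11 over the 6698 transcripts over 9 in both lines, and when differences were measured from that median, 3950 transcripts were higher in Mbn2 and 3579 higher in Kc, of which 1838 and 1357 were so by at least 2-fold. The calls under 2-fold leaned towards Kc before this shift, at 1680 in Mbn2 and 2625 in Kc. After it they were nearly even, at 2112 in Mbn2 and 2222 in Kc. Without limma's moderation of the variances, 1768 were higher in Mbn2 and 2134 in Kc.

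**Figure D1:**
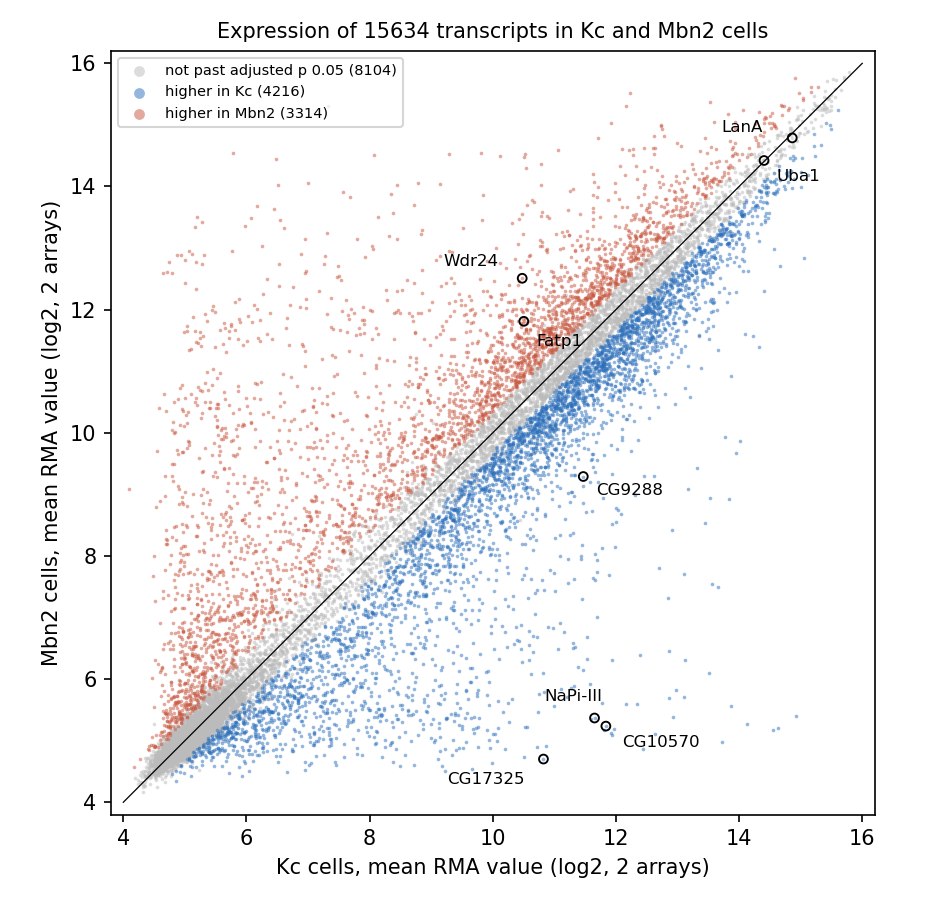
Mean log2 RMA value of each of 15634 transcripts in Kc cells (x axis) and Mbn2 cells (y axis), 2 arrays per line; the line marks equal values, colours mark transcripts past an adjusted p of 0.05, and 8 named transcripts are circled. The 3314 transcripts higher in Mbn2 and the 4216 higher in Kc include transcripts near the bottom of the scale in one line and in the upper range in the other.

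Most transcripts held the same broad level in both lines. Transcripts were divided by line means into dim (under 6) and bright (over 8), limits set after the data were seen. By these limits, 7687 transcripts (49.2%) were bright in both lines and 4586 (29.3%) were dim in both, while 2907 lay between the limits in at least one line and belong to neither group there. A switch from one side of both limits to the other was seen for 261 transcripts that were dim in Kc and bright in Mbn2, with a median difference of 4.37 log2 units, and for 193 that were bright in Kc and dim in Mbn2, with a median difference of -3.89. All of these passed the test. Among transcripts bright in both lines, 60.4% differed, 1901 towards Mbn2 and 2742 towards Kc, and among those dim in both 9.62% differed. The lean towards Kc in the bright group was not recounted with differences centred on bright transcripts, which reversed the majority of all calls. Stricter limits of 5.5 for dim and 9 for bright left 102 and 72 switched transcripts.

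Among the 44 transcripts that could be named, 6 were higher in Mbn2, 19 were higher in Kc and 19 did not pass the test. The same numbers, 6 and 19, passed when p-values were adjusted over the named transcripts alone. Of the 17 with 1 gene symbol, 5 were higher in Mbn2 and 3 in Kc. Of the 27 that carry reading frames of several named genes, 1 was higher in Mbn2 and 16 in Kc.

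Wdr24 (FBtr0085543), which encodes a subunit of the GATOR2 complex that activates TORC1 signalling, was 4.09-fold higher in Mbn2. Its values were 10.48 ± 0.01 in Kc and 12.51 ± 0.06 in Mbn2 (log2, SD, n = 2), a difference of 2.03 with a standard error of 0.10 and an adjusted p of 4.74e-05. The GATOR2 subunit mio (FBtr0077835) did not pass the test, with a difference of 0.19 (95% interval -0.05 to 0.44, adjusted p = 0.166, and 0.038 to 0.384 over the alternatives). Fatp1 (FBtr0080133), a fatty acid transport protein, was 2.47-fold higher in Mbn2, at 10.50 ± 0.11 in Kc and 11.81 ± 0.06 in Mbn2 (difference 1.31, standard error 0.11, adjusted p = 0.000362). The roadkill gene rdx (FBtr0082871), whose product is a substrate adaptor of Cullin-3 ubiquitin ligases that targets the Hedgehog effector Ci, was 1.77-fold higher in Mbn2 (difference 0.82, standard error 0.11). His4r (FBtr0082962), the histone H4 gene outside the replication-dependent histone cluster, was 1.63-fold higher in Mbn2 (difference 0.70, standard error 0.15). CG16974 (FBtr0080489) was 1.48-fold higher in Mbn2 (difference 0.56, standard error 0.11), but its adjusted p, 0.00895 in the full data and 0.00014 to 0.0724 over the alternatives, was 0.055 without Mbn2 replicate 2.

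In the other direction, NaPi-III (FBtr0076213), named for a type III sodium-phosphate cotransporter, was bright in Kc at 11.65 ± 0.08 and dim in Mbn2 at 5.37 ± 0.15 (log2, SD, n = 2). Its difference was -6.28 with a standard error of 0.12 (adjusted p = 3.62e-06) between RMA values, and its true size is unknown because Mbn2 was dim. The transcript of sle (FBtr0082231), which encodes the nucleolar protein slender lobes, was 1.88-fold higher in Kc (difference -0.91, standard error 0.11, adjusted p = 0.00128). CG31178 (FBtr0084138) was 1.92-fold higher in Kc (difference -0.94, standard error 0.22, adjusted p = 0.0171). Its Kc replicates were 8.78 and 8.17, and the adjusted p, 0.00253 to 0.194 over the alternatives, was 0.0802 without Mbn2 replicate 1.

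Of the 27 named transcripts with several reading frames, 16 were higher in Kc and 10 did not pass the test. They are those that a gene table records and were grouped after their values were seen, so they do not stand for all such transcripts. A single array value cannot tell the frames of such a transcript apart. FBtr0081122, which carries CG10570 and CG42502, was higher in Kc, at 11.84 ± 0.03 in Kc and a dim 5.24 in both Mbn2 samples (difference -6.60). FBtr0081102, which carries CG17325 and CG42305, was higher in Kc, at 10.82 ± 0.20 in Kc and a dim 4.70 ± 0.12 in Mbn2 (difference -6.12, and -5.44 with log2(value + 16)). FBtr0082829, which carries CG9288 and CG42375, was 4.53-fold higher in Kc, and FBtr0076348, which carries the N-terminal acetyltransferase gene vnc and CG42455, was 2.37-fold higher. The other 12 higher in Kc differed by 1.40-fold to 2.15-fold. They included the transcripts of Ppcdc, a coenzyme A synthesis enzyme (1.90-fold), Tim10, a chaperone of mitochondrial protein import (1.75-fold), Mettl5, an rRNA adenosine methyltransferase (1.67-fold), Mocs2B with Mocs2A, the molybdopterin synthase subunits (1.59-fold), Rad1, of the 9-1-1 checkpoint clamp (1.51-fold), and PIG-M, a mannosyltransferase of GPI anchor synthesis (1.46-fold). The transcript of PIG-P and Tcs6 was 1.58-fold higher in Kc, but its adjusted p, 0.000323 to 0.144 over the alternatives, was 0.0561 without Kc replicate 1 and 0.0698 without Mbn2 replicate 2. That of Pbp49 and CG42516 had an adjusted p of 0.000304 to 0.060 over the alternatives, the highest without Mbn2 replicate 1. The single transcript of this class higher in Mbn2 carries CG5116 and CG42488 (1.44-fold), with an adjusted p of 0.00115 to 0.0539 over the alternatives, the highest without Mbn2 replicate 2. Without moderation of the variances, 8 of the 25 named calls were lost, at adjusted p = 0.0672 to 0.194: His4r, CG16974, CG31178 and the transcripts of CG32573, Ppcdc, Mocs2B, PIG-P and CG7071.

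**Figure D2:**
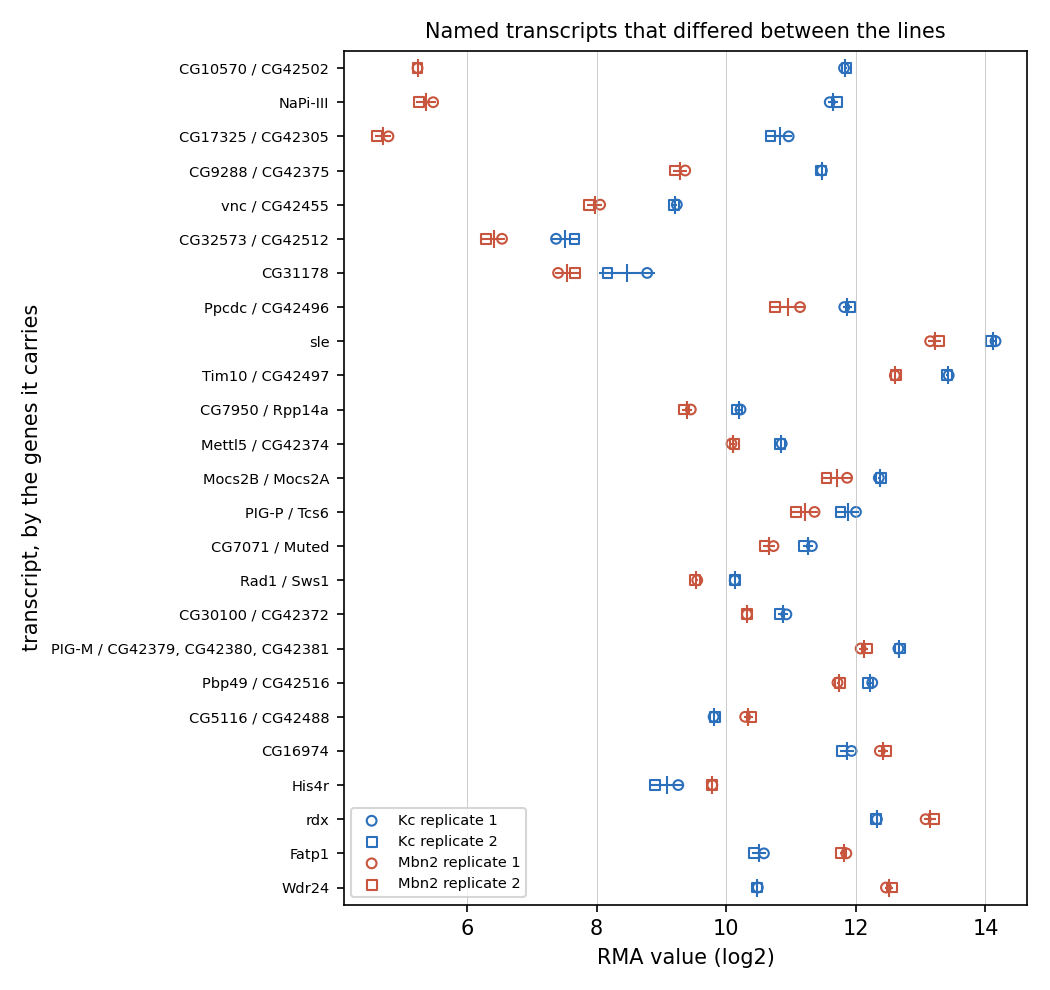
Log2 RMA value (x axis) of the 25 named transcripts that passed an adjusted p of 0.05, each labelled by its main gene and, after the slash, the genes of its upstream reading frames. Open symbols are the single samples and bars are the line mean with its SD (n = 2); the top 19 transcripts are higher in Kc and the bottom 6 in Mbn2.

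The 19 named transcripts that did not pass the test included 3 that were the only identified members of lists fixed beforehand. The lists were fixed, but the rule for named genes takes list members only past the threshold, so these 3 lie outside it. Like the others given here, they were chosen after their values were seen. The ubiquitin-activating enzyme Uba1 (FBtr0088499) had values of 14.40 ± 0.04 in Kc and 14.42 ± 0.04 in Mbn2 (log2, SD, n = 2), a difference of 0.02 with a 95% interval of -0.24 to 0.27; its sign varied with the setting, from -0.03 to 0.13. The laminin chain gene LanA (FBtr0077014), the only identified member of the extracellular matrix list, differed by -0.07 (interval -0.35 to 0.20), or by 0.04 when centred on bright transcripts, with a limma adjusted p of 0.638. FBtr0071140 carries CG45089 and the complex I subunit ND-MNLL, the only identified member of the respiratory chain list, and the array value cannot tell these frames apart. This transcript differed by -0.11, or by 0.01 with that centring, with a limma adjusted p of 0.478. The chromatin remodeller kis (FBtr0078144), the only member of the trithorax list, differed by 0.22 (interval -0.04 to 0.49), with a limma adjusted p of 0.147; over the alternatives this ranged from 0.0389 to 0.417, and it passed with an intensity trend and with centring on bright transcripts. Fatp1 was the only identified member of the list for lipid uptake and storage. With 1 member there is nothing to correct for, so the counts adjusted over the list alone, 1 of 1 for that list and 0 of 1 for the other 3, add nothing to those over all transcripts. The histone deacetylase HDAC3 differed by 0.11 (adjusted p = 0.454), and SuUR, a suppressor of DNA replication in heterochromatin, differed by -0.27 (adjusted p = 0.0864, and 0.0304 to 0.273 over the alternatives). The spectrin gene alpha-Spec differed by -0.19 (adjusted p = 0.201).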

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

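The direction of none of the 25 named calls changed under any alternative run, but this adds little support. The block, the trend, no moderation and the row filters leave a difference as it is. Both samples of a line lay above both of the other for every call, so leaving out 1 sample could not turn its sign. Centring on bright transcripts moved differences by 0.11, less than the smallest named call of 0.485. The counts of calls stayed within 1.5 times except as follows. Without moderation of the variances, 1768 transcripts were higher in Mbn2 and 2134 in Kc. With transcripts below the median left out, 864 were at least 2-fold higher in Mbn2 and 828 in Kc, and the dim-to-bright transcripts fell to 40 in the direction of Mbn2 and 20 in that of Kc, since that filter removes transcripts with a low mean. Limits of 5.5 and 9 gave 102 and 72. Leaving out single samples, where the lone sample is assumed to vary like the others, gave 2696 to 3021 transcripts higher in Mbn2 and 3232 to 3873 in Kc, 1637 to 1659 at least 2-fold higher in Mbn2, 1513 to 1718 in Kc, 256 to 267 dim in Kc and bright in Mbn2, and 187 to 199 the other way. Samples with the same replicate number did not deviate together (r = -0.05 across transcripts), and with a replicate block 3171 transcripts were higher in Mbn2 and 3963 in Kc; the block changed none of the 44 named results. Differences of uncalled genes near 0 changed sign. Uba1 was at -0.0292 after a second quantile normalization and at -0.0132 to 0.0471 without single samples. The transcript of ND-MNLL and CG45089 was at 0.0066 and LanA at 0.037 with differences centred on bright transcripts. That centring subtracted the same median, -0.11, from every difference, so it turns the sign of any difference between -0.11 and 0, whatever the gene. The values of Uba1 without single samples are differences between averages of the samples left. Its change after a second quantile normalization was not examined further. In the named transcripts, 14 of 346 alternative values of called transcripts lost the call, 8 of them without moderation, and 12 of uncalled ones gained it. That tally left out the adjusted p under 0.01 and treat against a fold of 1.5. Under 0.01, CG31178, His4r and the transcripts of PIG-P, Pbp49 and Mocs2B would lose the call, at limma adjusted p of 0.0103 to 0.0171. The named calls were not tallied with treat. The gene list and X chromosome tests and the collapse of rows to genes were not run, because too few rows have names. The table holds no signal over background, so what dim transcripts can show is limited by an unknown floor.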

Other observations

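All tests in this part were chosen after the results were seen. In 2 places named transcripts come from genes that lie next to each other in the RefSeq table, and both pairs moved together. The transcript of CG10570 and CG42502 and that of its neighbour CG17325 and CG42305 were both bright in Kc and dim in Mbn2, with differences of -6.60 and -6.12. The neighbours Tim10 with CG42497 and Ppcdc with CG42496 were both lower in Mbn2, by the smaller differences of -0.81 and -0.92. Both pairs belong to the named transcripts with several reading frames, of which 22 of 27 were lower in Mbn2, so a shared direction alone shows little. The other 2 splits of the 4 samples into 2 and 2 called 0 transcripts, against 7530 for the real split. Each of them put 1 sample of each line in each group, so the line difference became spread within the groups. Calls were therefore hardly possible there, and the contrast is no test of the real split. Only 1 of 3 splits, the real one, reached that count, and 3 splits are too few for a share under 0.05.

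Differences between the lines shifted together over long stretches of consecutive transcript numbers. The 6698 transcripts over 9 in both lines were put in the order of their FlyBase number and divided into 66 stretches of 100. The median difference of a stretch ran from -0.52, where 17% of transcripts were higher in Mbn2, to 0.49, where 75% were. The SD of the stretch medians was 0.21, against at most 0.10 in 1000 reshuffles of the rows, and 4 stretches lay below and 6 above every reshuffled stretch. Transcript numbers partly follow the chromosomes: of 43 pairs of named transcripts next to each other in number order, 33 were on the same chromosome arm, against at most 20 in 9999 permutations (p = 0.0001, the smallest they can give).

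Rows that repeat 1 gene do not account for the whole of these shifts, since with the first bright row kept of every 10 consecutive rows of the whole table, which left 1484 rows in 74 stretches of 20, the SD was 0.253, above the highest of 1000 reshuffles of those rows at 0.208. A regional artefact of single arrays is argued against by the stretch medians of the pair of replicate 1 arrays and the pair of replicate 2 arrays, which correlated at r = 0.966 (Spearman 0.947, permutation p = 0.0001; r = 0.959 without the 2 stretches farthest from the median), while replicates within a line gave an SD of 0.02. A trend with brightness left the SD at 0.212 once removed. A candidate explanation is that the lines differ in DNA copy number over chromosome segments, in which case brighter and dimmer members of a stretch would shift alike; their medians correlated across stretches at r = 0.808. Regional differences in gene regulation predict the same, and no DNA was measured here, so these cannot be told apart.

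The 27 named transcripts with several reading frames had a median difference of -0.56, with 22 of 27 lower in Mbn2. Of 10000 sets matched on the mean value, 1.04% were as low (their central 95% ran from -0.49 to 0.25). The median of up to 50 bright neighbours in number order on either side was then subtracted. This left a median of -0.42, and 1.49% of matched sets were as low. The class was picked after these same values were seen, and the sets drew each member independently although some of the 27 are neighbours. The shares therefore cannot decide whether brightness or regional shifts account for the lean. The hypothesis that such transcripts may as a class be lower in Mbn2 rests on 27 transcripts that a gene table happened to record, and growth medium remains untested.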
